A study of Danio rerio with 2 samples.

How the data were processed

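Total RNA was extracted from pools of 15 whole adult zebrafish hearts, amplified and biotin-labelled with an Affymetrix 3' IVT kit, per the labels' protocols, and measured on 2 arrays, 1 from water-exposed and 1 from atropine-exposed fish. The deposited table holds 1 log2 expression value per probe set and array. The scale and normalization method are not given in the sources used here. The log2 scale was inferred from the range of the values, and the sorted values of the 2 arrays differed by at most 0.15, with a 95th percentile of 0.03, as after a between-array normalization by the authors. Such a step sets the overall level of the arrays equal. The gene differences therefore do not show a global shift in RNA content, and each is relative to the other genes. Scanner files and detection calls were not used here, so whether a probe set was above background is unknown and depth in the sense of counts does not apply.

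Probe sets were named from the platform annotation, through Entrez identifiers matched to a RefSeq gene table of the GRCz12tu assembly, in which 99.2% of the named probe sets were found. Of 15502 non-control probe sets, 10795 had 1 symbol, 135 several and 4572 none. Those with several or no symbol were counted but not named. No genome coordinates are given, because the array's annotation names no build.

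The difference log2(atropine) minus log2(water) was taken as deposited, without re-centring. A probe set was compared if the higher of its 2 values was at or above 4.05, the median of all non-control values. A gene was represented by its probe set with the highest mean. The main counts are of probe sets at least 2-fold apart. With 1 array per group no test across samples is possible. Fold changes in the text are 2 to the power of the size of the log2 difference.

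Before the data were examined, 33 gene lists were fixed for the cell types, pathways and possible admixtures of the heart, of which 30 had at least 5 genes past the filter. Of 2129 list names, 1183 matched a symbol, 76 a synonym and 870 no named probe set. For each list the median difference was set against 10000 random lists of the same size drawn from 20 bins of mean level, with percentiles under 2 or over 98 called outside. The percentile describes these 2 arrays and is no test of the treatment. The genes named in the text were fixed by rule. They are the 15 largest differences of at least 2-fold per direction, leaving out clone names, up to 6 cholinergic genes past the filter, and per list up to 2 members higher and 2 lower by at least 1.5-fold, or else the 2 brightest. Genes named outside this rule are said to be so.

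On simulated arrays whose differences had a standard deviation of 0.15, 200 probe sets well above the level filter were changed by 1.5 or 2 (log2). All were recovered in the right direction, with 0 false calls among 7904 probe sets. Of 100 random lists of 25 genes 4 fell outside, near the share that the percentile limits fix in advance, so this is no check of the method. Of 100 such lists shifted by 0.15, 98 were called above. The simulated genes varied independently, and the real differences had a standard deviation of 0.28. A 2-fold threshold lay far outside the simulated noise, so recovery was near certain. The noise of the real arrays is not known, so these rates hold for that simulation only.

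The alternatives were median centring, quantile normalization, a loess fit on mean level (span 0.4), no filter or a filter at the upper quartile, an offset of 16 on the linear scale, leaving out probe sets that can take up related transcripts, 1 probe set or the mean per gene, thresholds of 1.5-fold and 3-fold, and lists without shared members. Scalings to the cardiomyocyte list and to the polyadenylated spike-ins were added after seeing the data. Offsets of 1 and 64 had been planned for linear values and were not run. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.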

Results

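Adult zebrafish regrow ventricular muscle after part of the ventricle is cut away. In this study about 20% of the ventricle, at the apex, was removed from adult fish, which were then kept in water or in atropine, a blocker of muscarinic acetylcholine receptors, the receptors through which the vagus nerve acts on the heart. Whole hearts were collected 24 hours after the amputation, and total RNA from a pool of 15 hearts per condition was measured on 1 Affymetrix zebrafish expression array. The design therefore asks which transcripts differ early in regeneration between hearts exposed to atropine and hearts exposed to water. It holds 2 arrays, 1 per condition, and no replicates, so no difference below has a replicate check or a p-value. Each value describes these 2 pools, and the number of arrays limits the precision.

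The deposited log2 values covered 15617 probe sets, of which 115 were manufacturer's controls. They ran from 2.02 to 14.05, with near-equal distributions on both arrays. The 2 arrays correlated at r = 0.994 across the 15502 non-control probe sets, which are not independent replicates. The higher of the 2 values reached the overall median in 7961 probe sets, which represented 5294 genes with a single symbol, and these were compared. Their differences, atropine minus water on the log2 scale, had a median of -0.01 and a standard deviation of 0.28.

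The classes of control probe sets differed between the arrays by unlike amounts. The 13 probe sets for transcripts added at hybridization that passed the level filter differed between the arrays by a median of -0.05, with extremes of -0.13 and 0.06. The 13 for polyadenylated bacterial transcripts that passed it were all lower on the atropine array, with a median of -0.48 and extremes of -0.86 and -0.13. By the manufacturer's scheme these transcripts are added to the RNA before labelling. Why they were lower was not tested. Differences below are as deposited, without re-centring, and are to be read against the median of -0.01. A scaling to the polyadenylated spike-ins would put that median at 0.47 and one to the cardiomyocyte genes at 0.13. The 5' and 3' control probe sets of zebrafish GAPDH differed between the arrays alike, by 0.17 each. Those of actin were lower on the atropine array by unequal amounts, at -1.03 for the 5' and -0.58 for the 3' probe set. A second actin 5' probe set, which can also take up related transcripts, was at -0.82. The middle actin probe set was at -0.48, nearer 0 than the 3' one.

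**Figure D1:**
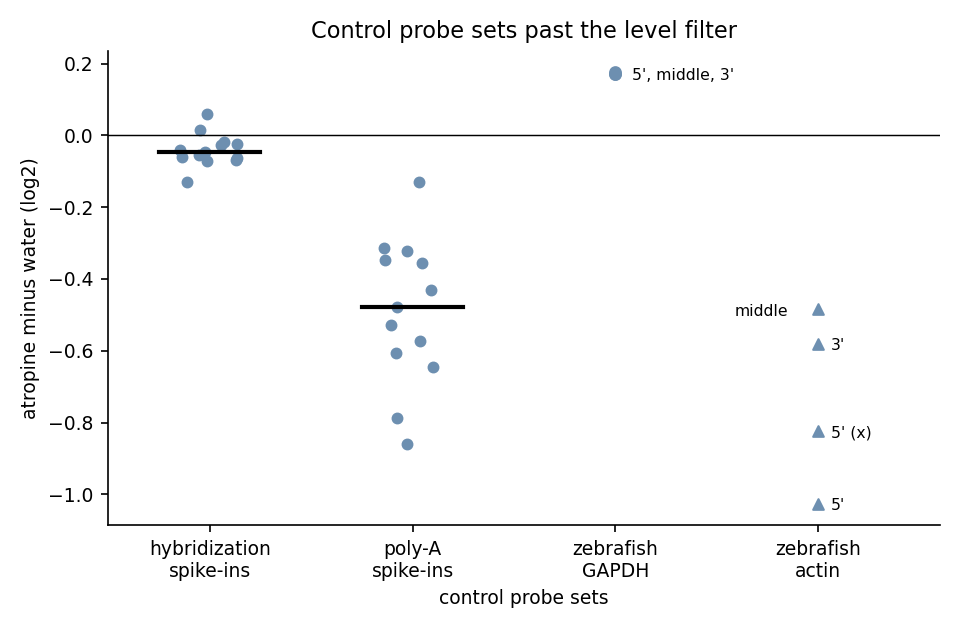
Difference between the arrays (atropine minus water, log2) of control probe sets that passed the level filter, 1 point per probe set, with black bars at the medians of the spike-in classes; (x) marks a probe set that can also take up related transcripts. Hybridization spike-ins lie near 0 (median -0.05), and all 13 polyadenylated spike-ins lie below it (median -0.48).

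Of the 15 named genes with the largest differences toward lower values in atropine-exposed hearts, 5 are in the macrophage or neutrophil lists described below. The 15 include cd74a and cd74b, which encode the invariant chain of MHC class II molecules and were 3.09-fold and 2.49-fold lower. The matrix metalloproteinase genes mmp9 and mmp13a were 2.69-fold and 2.304-fold lower, and fn1a, encoding fibronectin, was 2.93-fold lower. The interferon-induced GTPase gene mxa was 2.61-fold lower, cfd (complement factor D) 2.27-fold, ifi30a (a lysosomal thiol reductase) 2.13-fold and the tetraspanin gene cd9b 3.19-fold. The NK-lysin gene nkl.4 was 2.22-fold lower. In atropine nkl.4, mxa and krt5 stood at 2.91, 3.75 and 3.77, below the filter, so their folds are uncertain, and with an offset of 16 on the linear scale they differed by -0.48, -0.79 and -0.71 (log2). Of contractile genes, tnnc1a (cardiac troponin C) was 2.66-fold lower. The gene now called myh7, formerly vmhc, a ventricular myosin heavy chain with close relatives that its probes might not separate, was 2.28-fold lower. The remaining 3 were znf106a (3.14-fold), krt5 (2.39-fold) and gda, encoding guanine deaminase (2.15-fold). With the offset gda (-0.79), ifi30a (-0.96) and myh7 (-0.99) also came under 2-fold.

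Genes with the largest differences toward higher values in atropine were of other kinds. The phosphate transporter gene slc20a1a was 3.59-fold higher and pfkfb4b, whose product controls glycolytic flux, 3.31-fold higher. The ferritin-like gene fthl28 was 2.86-fold higher, the adult beta-globin gene hbba2 2.52-fold, and hif1al, a hypoxia-inducible factor gene also called Hif-3alpha, 2.43-fold. The water channel gene aqp8a.1 was 2.33-fold higher, the heart and fin transcription factor gene tbx5a 2.36-fold, mibp 2.23-fold and gbp 2.39-fold. The DNA damage response gene gadd45aa was 2.09-fold higher and the chaperone gene hsp90aa1.2 2.06-fold. The others were nt5dc2 (2.202-fold), nsg2 (2.16-fold, from 3.97 in water, below the filter), dnase1l4.1 (2.12-fold) and hdr (2.12-fold). A second probe set of hsp90aa1.2 differed by 0.84 (log2) in the same direction, and a second one of hdr by 0.20. With the offset 7 of these genes came under 2-fold, at log2 differences of 0.97 for fthl28, 0.95 for tbx5a, 0.94 for hsp90aa1.2, 0.79 for hdr, 0.70 for dnase1l4.1, 0.68 for gadd45aa and 0.65 for nsg2. With the mean of their probe sets hsp90aa1.2 and hdr did too, at 0.94 and 0.64. Ferritin, globin and hsp90 genes have near-identical copies, so their single-gene values are uncertain.

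In all, 28 probe sets were at least 2-fold higher and 37 at least 2-fold lower in atropine, together 0.82% of those compared. At 1.5-fold the numbers were 168 and 182. For 648 genes with several probe sets, the 2 brightest differed in the same direction in 71.5% (95% Wilson interval 67.9 to 74.8), and their differences correlated at r = 0.69 across genes. Where the brightest probe set was at least 1.5-fold apart, the direction was shared in 26 of 27 genes. These probe sets measured the same 2 RNA pools, so their agreement bears on measurement error only.

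**Figure D2:**
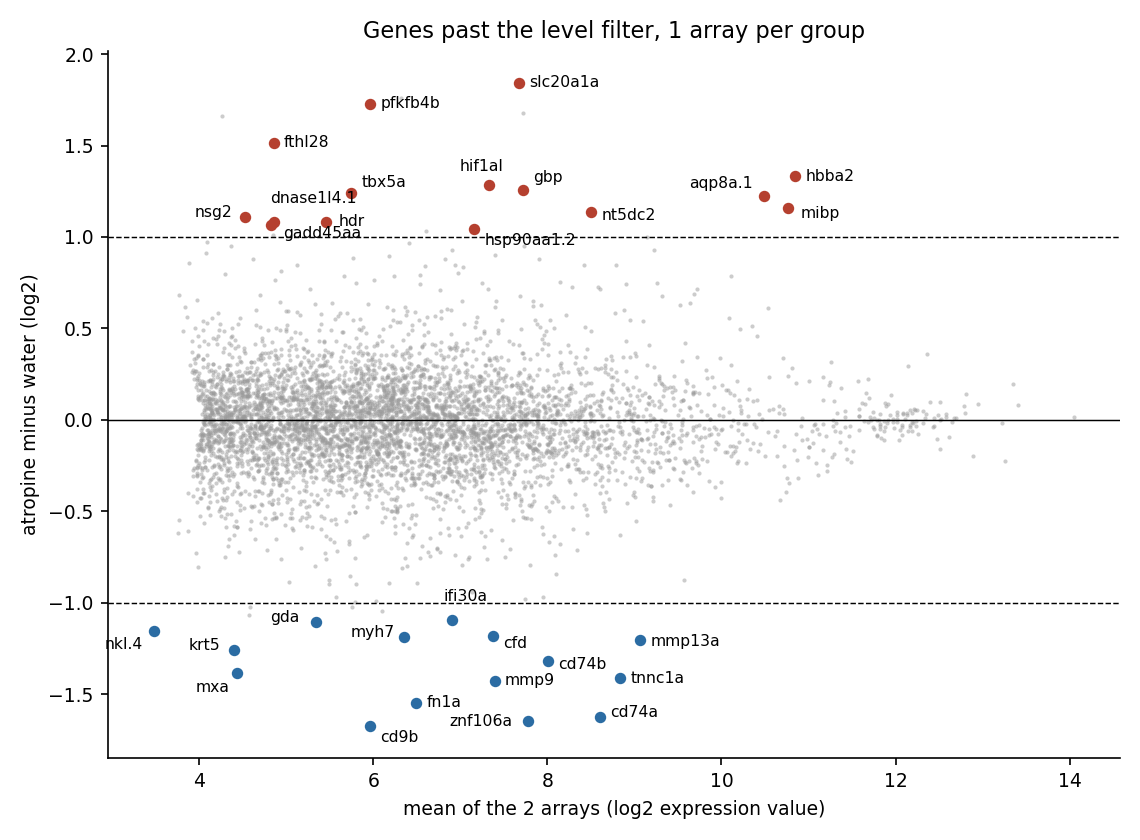
Difference between the arrays (atropine minus water, log2) against the mean of the 2 arrays (log2) for 5294 genes, 1 probe set each; dashed lines mark 2-fold. Labelled points are the 15 genes with the largest difference in each direction, red where higher and blue where lower in atropine, leaving out genes known only by clone names.

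Gene lists fixed before the data were examined were set against 10000 random lists of the same size matched on mean level. Among 30 lists with at least 5 measured genes, 13 medians lay below the 2nd percentile of the random lists and 4 above the 98th. If their members were random draws of genes, 1.2 of 30 would fall outside. That number does not hold for genes that vary together, as members of a list can. Several lists share genes. For 7 of the lists within the random lists the sign of the median turned under at least 1 alternative, so no direction is given for the muscarinic signalling, neuronal, cytokine, endothelial, cardiac transcription factor, heat shock and ribosomal protein lists.

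Neutrophil and macrophage markers were lower in atropine-exposed hearts. The 15 neutrophil genes had a median of -0.45, below all 10000 random lists, with 7 at least 1.5-fold lower and none that much higher. The size of the median depended on the processing. It was -0.22 over 12 genes (percentile 0.43) without probe sets that can take up related transcripts, -0.28 with the offset and -0.69 over 12 genes without members shared with other lists. Besides mmp9 and mmp13a, the granule genes mpx (myeloperoxidase) and lyz (lysozyme) were 1.99-fold and 1.74-fold lower, while srgn differed by 0.16 (log2). These 3 were picked after their values were seen. On the same arrays red blood cell genes were higher, as given below. The 38 macrophage and antigen-presentation genes had a median of -0.24, also below all random lists, with 7 at least 1.5-fold lower and 2 at least 1.5-fold higher. The 2 were cathepsin genes, ctsl.1 at 0.80 (0.44 with the offset and 0.55 with the mean of its probe sets, from a level of 3.90 in water) and ctsba at 0.61. The 21 interferon and class I genes had a median of -0.27 (percentile 0.01), with mxa and irf7 (-0.75) lowest and none at least 1.5-fold higher.

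The complement and acute phase list had a median of -0.48 over 8 genes, below all random lists, with cfd and c1qc (-0.79) lowest. Most of the 8 are complement genes, so the median says little of acute phase genes. The 7 liver markers that passed the filter had a median of -0.49, and the lowest of them, apoeb (-1.02) and apoc1 (-0.72, or -0.42 with the offset), are apolipoprotein genes that also stand in the macrophage list. Neither call held with no level filter, where the complement median was -0.0535 over 33 genes (percentile 3.97) and the liver median 0.0086 over 48 genes (percentile 46.5). Without shared members the complement median was -0.31 over 6 genes. Cytokine and NF-kB genes had a median of -0.03 over 21 genes, within the random lists (percentile 38.5), with medians from -0.13 (percentile 2.21, without probe sets that can take up related transcripts) to 0.06 (percentile 88.2, without shared members) under alternatives. The acute phase gene saa, which stands in this cytokine list, was 1.95-fold higher. Of the others, nfkbiab differed by 0.59 (log2), and socs1a was 1.58-fold lower. With the offset nfkbiab (0.56) and socs1a (-0.51) came under 1.5-fold, as did socs1a with the mean of its probe sets (-0.582). The list meant for lymphocytes gave no result. Its median of -0.04 (percentile 42.5) is the value of polr1g, an RNA polymerase I subunit gene that is no lymphocyte marker and is named after its value was seen, and the other 4 measured genes, from 0.39 to -1.15, are under the minimum of 5.

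The extracellular matrix and fibroblast list and the epicardial list were also lower. The 28 matrix genes had a median of -0.33, below all random lists, with 7 at least 1.5-fold lower and none at least 1.5-fold higher. With no level filter it was -0.12 over 54 genes, again below all random lists. The collagen gene col1a2 differed by -0.98, and by -1.22 on its second probe set. The 20 measured genes of the epicardial list had a median of -0.21 (percentile 0.01). The list's markers tcf21, tbx18, wt1a and wt1b, named here outside the rule, gave no value past the filter. Several of the 20 also stand in other lists, so the median does not stand for the epicardium alone. Among the 20, fn1a, which is in both lists, and the keratin gene krt4 (-0.97) were lowest. The gene aldh1a2, encoding the retinoic acid-synthesizing enzyme that the injured epicardium and endocardium make, differed by -0.40. Endothelial genes had a median of -0.03 over 32 genes (percentile 33.6), with aqp8a.1 and the blood and vessel transcription factor gene tal1 (0.85, or 0.58 with the offset) highest. Smooth muscle genes had a median of -0.11 over 14 genes (percentile 7.15), and one of -0.28 over 10 genes, outside the random lists, without shared members or with the filter at the upper quartile.

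Red blood cell genes were higher in atropine-exposed hearts. The 28 genes had a median of 0.41, above all 10000 random lists, with 11 at least 1.5-fold higher and none at least 1.5-fold lower. Beside hbba2, the erythroid transcription factor gene klf1 was 1.84-fold higher, and gata1a, named here after its value was seen, differed by 0.84. The globin gene with the highest level, hbaa1, stood near the top of the range and differed by 0.20; it too was picked after its value was seen. Of the 11 genes, tmod4 is also in the cardiomyocyte list, tal1 in the endothelial and nfe2 in the thrombocyte list. In thrombocyte genes the median was -0.07 over 7 genes (percentile 27.3), with nfe2 at 0.75, or 0.58 with the offset.

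Heart muscle and mitochondrial genes had medians slightly below 0. The 35 cardiomyocyte genes had a median of -0.14 (percentile 0.06) and a standard deviation of 0.38, with 22 below 0, 2 at least 1.5-fold lower, tnnc1a and myh7, and 1 higher, tmod4 at 0.88 (0.53 with the offset). The abundant cardiac transcripts myl7 and tnnt2a, picked after their values were seen, differed by -0.02 and 0.00. Of 99 respiratory chain and citric acid cycle genes 86 were below 0, and their median of -0.13, with a standard deviation of 0.15, lay below all random lists, although none was 1.5-fold lower. The exception in size was slc25a4, an ADP/ATP carrier gene, at 0.63, or 0.45 with the offset. The respiratory chain median was close to the cardiomyocyte one, and a scaling to the cardiomyocyte genes would put it just above 0. The 38 fatty acid genes had a median of -0.15 (percentile 0.1) and the 12 skeletal muscle genes one of -0.21 (percentile 0.1). The skeletal muscle call did not hold without members shared with other lists (-0.0614 over 6 genes, percentile 34.01) or with no level filter (-0.0571, percentile 2.40). Glycolysis genes lay above the random lists by a narrow margin, with a median of 0.06 over 31 genes (percentile 98.6). They lay within the random lists under 6 of the 9 alternatives, with a median of 0.00 after quantile normalization. Ribosomal protein genes had a median of -0.00 over 74 genes (percentile 72.9).

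**Figure D3:**
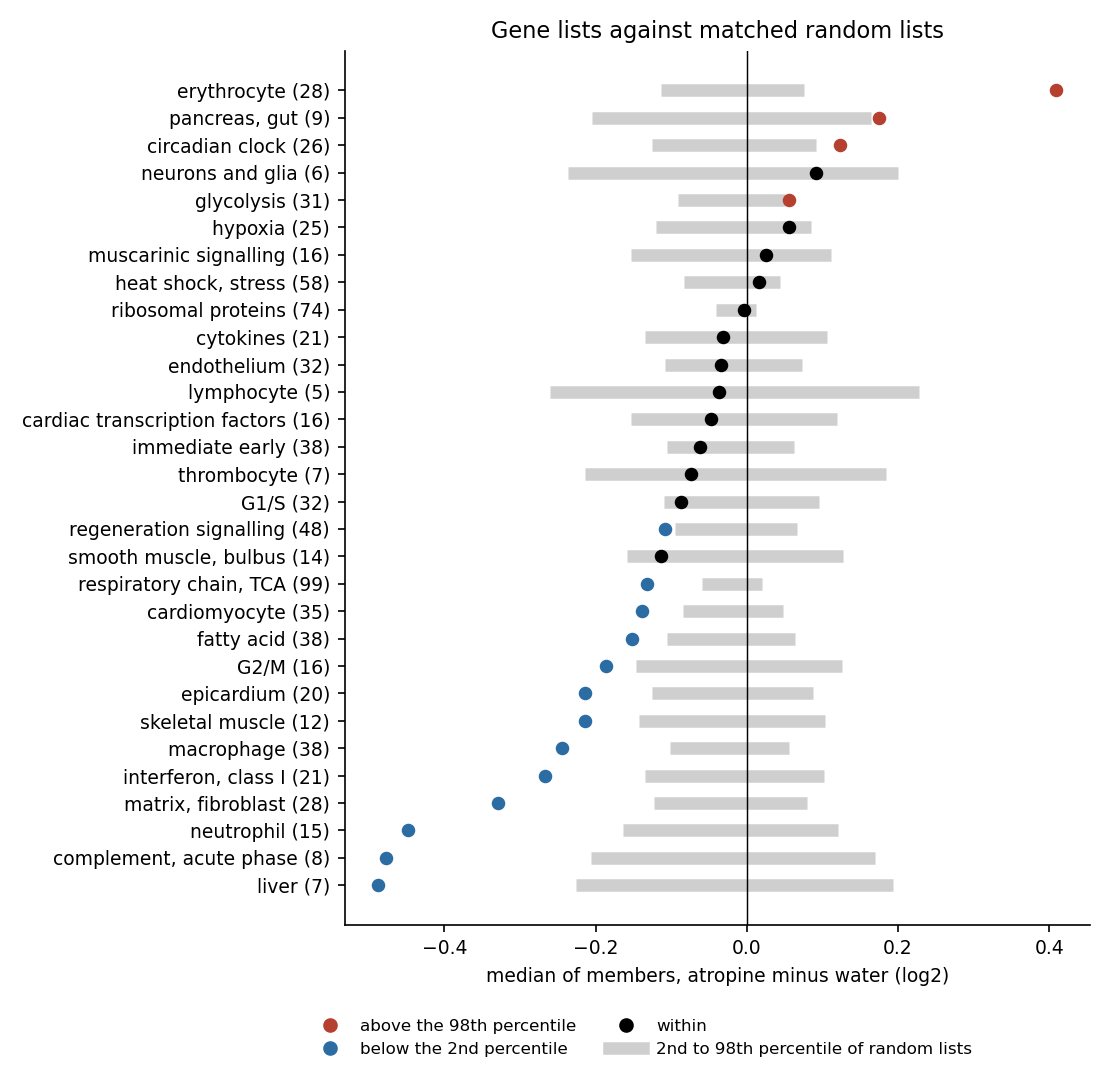
Median difference of each gene list's members (atropine minus water, log2; points) against the 2nd to 98th percentile of 10000 matched random lists (grey bars), with the number of genes in parentheses. The neutrophil median (-0.45) lies farthest below 0 among lists of at least 15 genes and the erythrocyte median (0.41) farthest above.

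Cell cycle and regeneration genes showed small differences. The 16 G2/M genes had a median of -0.19 (percentile 0.51). Yet the only members at least 1.5-fold apart were higher, kif20a (0.85) and tacc3 (0.71, or 0.50 with the offset). They encode a mitotic kinesin and a spindle protein and stood at 8.37 and 4.91 in water, where ccnb1 stood at 4.14. The mean of the G2/M list was -0.03. Its median was -0.066 over 63 genes with no level filter (percentile 0.19) and lay within the random lists with the filter at the upper quartile (-0.18 over 5 genes, percentile 11.5). The 32 G1/S genes had a median of -0.09 (percentile 5.72), with the replication licensing gene cdt1 at 0.97 (0.50 with the offset, from a level in water below the filter). With no level filter the G1/S median was -0.0620 and lay outside (percentile 1.60). The 48 regeneration signalling genes had a median of -0.11 (percentile 0.75) and no member at least 1.5-fold apart. It lay within the random lists with no level filter (-0.0387, percentile 4.41) and without shared members (-0.10, percentile 2.38). Cardiac transcription factor genes had a median of -0.05 over 16 genes (percentile 34.9), and tbx5a was the only one at least 1.5-fold apart.

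Among cholinergic genes few gave a usable signal. Of 8 with a probe set, chrm2a alone passed the level filter, at 5.41 in water and 5.49 in atropine. It encodes the M2 muscarinic receptor of the heart and is the only one of the 8 for a receptor that atropine blocks. The other 7 encode nicotinic receptor subunits, the enzyme that breaks down acetylcholine and its vesicular transporter. They had values between 2.58 and 3.29, too low to show a difference at this sensitivity. The 16 genes of muscarinic signalling had a median of 0.03 (percentile 73.8) and none was 1.5-fold apart; the brightest, gnb1b and gng5, differed by -0.01 and -0.15. The 2 adrenergic genes that passed the filter, mao and adra2b, differed by -0.12 and -0.08 (-0.21 for adra2b with the mean of its probe sets). The 6 neuronal and glial genes had a median of 0.09 (percentile 84.8).

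Circadian clock genes were higher in atropine. The 26 genes had a median of 0.12 (percentile 99.6), with 3 at least 1.5-fold higher and none lower by that much. The transcription factor gene tefa was 1.84-fold higher, with 0.63 (log2) on its second probe set, and nr1d2a 1.61-fold higher, from a level of 3.43 in water that lay below the filter, or by 0.31 (log2) with the offset. Immediate early genes had a median of -0.06 over 38 genes (percentile 15.2), with gadd45aa and klf9 (0.93) highest and junba (-0.63, or -0.581 after quantile normalization, just under 1.5-fold) lowest. Heat shock and stress genes had a median of 0.02 over 58 genes (percentile 86.1), with hsp90aa1.2 and fkbp5 (0.71) highest, and hypoxia genes one of 0.06 over 25 genes (percentile 92.3), with pfkfb4b and hif1al highest and p4ha1b (-0.72) and rbp4 (-0.63) lowest. Without shared members the hypoxia median was 0.23 over 12 genes (percentile 99.9). Pancreas and gut genes had a median of 0.17 over 9 genes (percentile 98.7), and none was 1.5-fold apart. With no level filter their median was 0.0321 over 35 genes, within the random lists. Of germ line genes dnd1 and ccnb1 passed the filter and differed by 0.11 and -0.42. In atropine ccnb1 stood at 3.72, below the filter, and it differed by -0.20 with the offset.

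**Figure D4:**
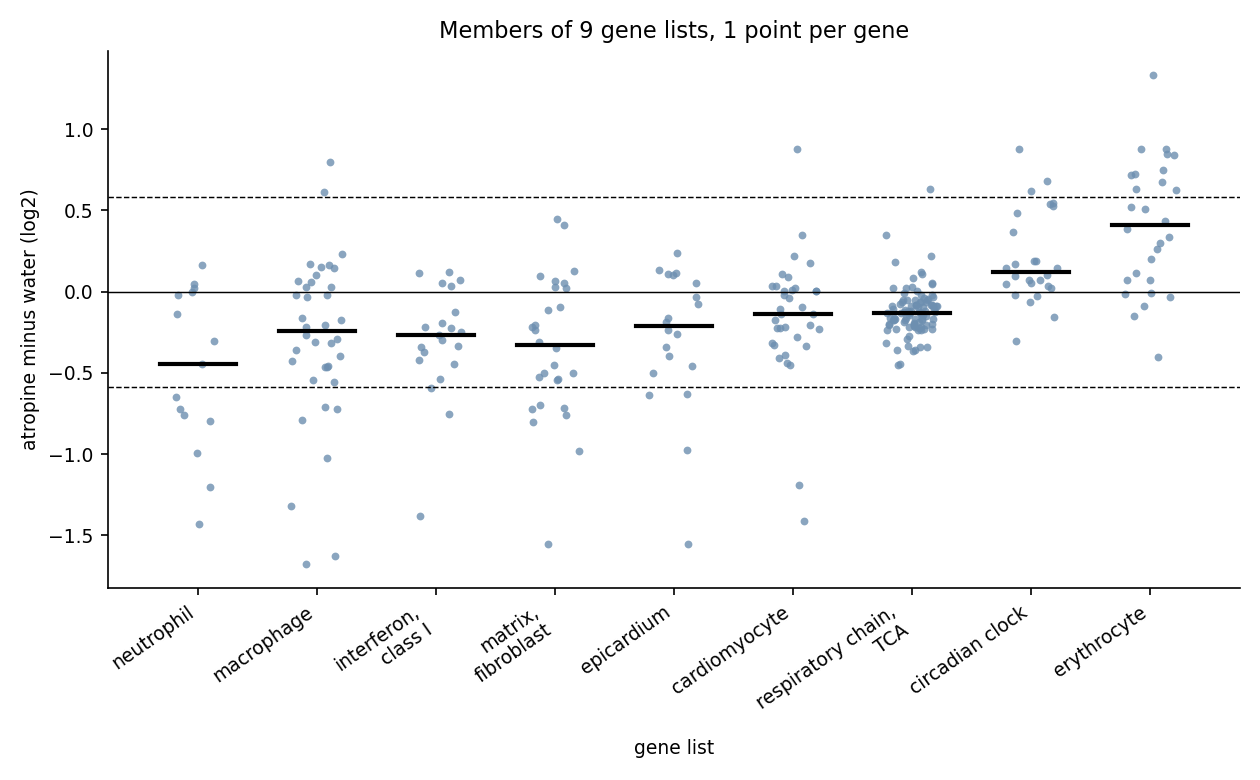
Difference between the arrays (atropine minus water, log2) of each member of 9 gene lists, 1 point per gene, with black bars at the medians and dashed lines at 1.5-fold. Members of the neutrophil and matrix lists reach -1.43 and -1.55, the respiratory chain genes sit close together around -0.13, and most erythrocyte genes lie above 0.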

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

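With 1 array per group no result could be checked by leaving out a replicate. No paired analysis was possible, because the sample labels give no pairing and each group holds 1 pool. The counts of probe sets at least 2-fold higher and lower (28 and 37) became 14 and 20 with an offset of 16, 168 and 182 at 1.5-fold, and 9 and 10 at 3-fold. The lower count was 22 with the filter at the upper quartile, 19 with 1 probe set per gene and 21 with a gene's mean, where fewer features were counted by construction. Of the scalings added after seeing the data, the cardiomyocyte list gave 46 higher, and the polyadenylated spike-ins 224 higher and 11 lower. The latter adds 0.48 to every difference, so 12 of the 13 lists below the random lists would have a median above 0 while their place among other genes stays the same. With the cardiomyocyte scaling 2 of the 13, respiratory chain and regeneration signalling, would have a median above 0, and 10 would stay below it. The share of genes whose probe sets agree in direction was 62.3% with no filter and 80.1% at the upper quartile. Median centring moves all genes alike, so it cannot change a list's place among random lists. Of 262 list medians under alternatives, 244 stayed on their side of the random lists, those under median centring by construction. The neutrophil, macrophage, interferon, matrix, epicardial, cardiomyocyte, respiratory chain, fatty acid, erythrocyte and clock lists did so under each of the 9 run, although the neutrophil median ranged from -0.69 to -0.22 and the matrix median from -0.45 to -0.12. With no filter the liver median reversed to 0.0086 and complement (-0.0535), regeneration signalling (-0.0387), glycolysis (0.0305), pancreas and gut (0.0321) and skeletal muscle (-0.0571) came within the random lists, while G1/S (-0.0620) fell outside. Glycolysis also came within under quantile normalization (0.00), loess (0.0599), the upper-quartile filter (0.0052), the offset (0.0384) and without shared members (0.0583). At the upper quartile G2/M (-0.18) came within and smooth muscle (-0.28) fell outside. Without shared members smooth muscle (-0.28) and hypoxia (0.23) fell outside, and regeneration signalling (-0.10) and skeletal muscle (-0.0614) came within. Of 593 values of named genes 29 lost their threshold, most with the offset, and the 2 that reversed were gnb1b, at 0.0014 after quantile normalization and 0.0205 after loess. Except where stated the cause was not tested. Low signal limits receptor, cytokine and cell cycle genes, many of which lie near the floor of the arrays.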

Other observations

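The tests of dilution by blood, of red cell RNA and of RNA quality, and the families by symbol, were chosen after the results were seen. Dilution was tested first by the interval of a difference of medians, which decided nothing, and only then by the count of members given below. The genes fbxo32, foxo3b, tsc22d3, npas2, bmal1a, hbae3, hbbe2 and hbaa1 are named below outside the rule for named genes, after their values were seen. So are clocka, clockb, bmal1b and rorcb. Genes of the mitochondrial ribosome were lower in the atropine array beside those of the respiratory chain, with medians near the cardiomyocyte median of -0.14. Among 35 families formed from symbols with a common stem and at least 12 genes, 5 lay outside the random lists, where 1.4 would by such draws. Of the mrpl genes, which encode proteins of the large mitochondrial ribosomal subunit, 34 of 36 were below 0, with a median of -0.15 (percentile 0.29), and of the mrps genes of the small subunit 15 of 20 were (median -0.14, percentile 1.87). The cox genes of cytochrome oxidase had a median of -0.14, with 17 of 19 below 0. Most of these cox genes stand in the respiratory chain list already seen to be lower, so their call largely restates it. The rnf genes, most of which encode RING-finger proteins, were higher, with 21 of 26 above 0 and a median of 0.18, above all 10000 random lists, and the fam genes, a stem with no shared function, lay just outside at 0.10 (percentile 98.1).

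The single largest differences belonged to probe sets with no single gene symbol. Dr.513.1.S1_at, which the annotation assigns to 2 genes, stood at 3.10 in water, below the level filter, and at 7.14 in atropine, so its fold of 16.4 is uncertain and was 6.38 with an offset of 16. Dr.9117.1.A1_at, with no symbol, was 8.60-fold lower (8.11 and 5.01), or 6.07-fold with the offset. Of the probe sets at least 2-fold apart, 5 of those higher and 16 of those lower had no single symbol.

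The markers of neutrophils, macrophages and matrix were lower in the atropine array while red cell genes were higher. Dilution by RNA of blood cells was taken to lower all other transcripts alike, and the cardiomyocyte median of -0.14 was taken as that level. Both are assumptions. Blood RNA also holds transcripts of leukocytes and transcripts shared by most cells. The median over all compared probe sets was -0.01 and that of ribosomal protein genes -0.00. The first test left dilution open, since the differences from the cardiomyocyte median were -0.31 (bootstrap interval over genes -0.72 to 0.15), -0.11 (-0.32 to 0.14) and -0.19 (-0.48 to 0.05). In the later test 5 of 15 neutrophil, 6 of 38 macrophage and 4 of 28 matrix genes lay at least 1.5-fold below it, reached by 0%, 0% and 0.4% of random lists centred there, against 5.85% for the 2 of 35 cardiomyocyte genes. Those members lay lower than a uniform shift to the assumed level would put random genes. The count does not decide on dilution, because these lists were picked for being low already. The test was also picked after another had failed to decide, and its null was corrected once. Treatment with atropine, fewer leukocytes by chance or handling, and a different extent of injury cannot be told apart with 1 pool per group.

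For the higher red cell genes, more red blood cell RNA in the atropine pool could not be tested apart from the list itself. The 16 red cell genes picked for it, of which 13 (81.2%) were above 0, are all members of the list already seen to be higher, so their count only restates it. The 4 globin genes do not decide it either, since hbaa1 lies near the top of the range (13.45 in atropine) and hbae3 and hbbe2 near the level filter (3.99 and 4.56 in atropine), which leaves hbba2 (1.33). A difference in RNA quality stays open too, because the 5' minus 3' contrast between the arrays was -0.0011 for the GAPDH control and -0.45 for the actin control. The middle actin probe set does not lie between the 5' and 3' ones. For the polyadenylated spike-in dap, whose 5' probe sets stood near the level filter, the contrast was -0.21 and, on other probe sets, 0.14. More red cell RNA, a change within red cells and an effect of atropine cannot be told apart with 1 pool per group.

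The higher clock list could reflect a different circadian phase of the 2 pools or a glucocorticoid-type response, ideas that came from the values of tefa, nr1d2a, klf9 and fkbp5. Both tests were fixed on genes whose single values had not been looked at, and igfbp1a, which had, was then taken off the list. For phase, the median of 8 output genes was 0.34 (percentile 99.98), though these stand in the clock list already known to be higher. The median of 7 genes picked for the activator arm, predicted below 0, was 0.032 (bootstrap interval -0.026 to 0.19). Of these, clocka, clockb, bmal1b and rorcb stood at 4.06, 4.34, 4.42 and 3.93 in water, near the level filter. Such low values leave little room for a fall. The median was 0.025 over 9 genes with npas2 (-0.30) and bmal1a (-0.16), left out because their lower values had been seen. By the criterion fixed beforehand a median at or above 0 counts against a phase difference, so the prediction failed. The interval, which that criterion did not use, includes values below 0, so the test does not exclude a phase difference. For 22 glucocorticoid-responsive genes the median was 0.15 (percentile 99.88, bootstrap interval -0.03 to 0.23), with fbxo32 (0.62) and foxo3b (0.54) highest and the classical target tsc22d3 at -0.16. Either remains a hypothesis, and so does an effect of atropine or of the hour of collection.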
